A study of Mus musculus with 8 samples.

How the data were processed

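Expression was measured in the microdissected genital tubercle region of FVB/N mouse embryos at embryonic day 14, in 4 males and 4 females. Per the labels, samples were not pooled, total RNA was extracted with a column kit, amplified in 2 rounds, labelled with biotin and hybridized to Affymetrix MOE430 arrays. The labels do not say whether samples share a litter, an amplification or a hybridization day. The deposited intensity of each probe set is on a linear scale and was made with GCOS, the Affymetrix scanner software, per the submitters' processing notes; its version is not given in the sources used here. The 2%-trimmed mean of each column was 1499.6, so the deposited values were treated as already scaled and were not normalized again. Samples were grouped by the sex in the labels.

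The table held 45101 probe sets, of which 64 were control probe sets. Of the others, 34945 named 1 gene, 932 several and 9160 none in the platform annotation, and 34741 of those with 1 gene matched the reference gene table (GRCm38.p6), which gave the chromosome; 0 symbols were updated. Genes were named only from probe sets with 1 gene, and some genes fixed for naming were not analysed here. Of the 107 genes given with values, 18 were read on probe sets whose suffix marks probes shared between transcripts or prone to cross-hybridization, among them Hbb-y, Rps14, Rps9, Krt14, Ccne1, Tbx3 and Xist. The authors' linear values were transformed as log2(value + 16). Control probe sets were left out, and probe sets with a mean log2 value over all 8 arrays at or above the median of these means (7.77) were tested, 22519 in all.

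The test was limma (version 3.58.1, R version 4.3.3) with lmFit and eBayes with a mean-variance trend, sex as the only term, and Benjamini-Hochberg adjustment over the tested probe sets with a threshold of 0.05. Each gene was represented by its tested probe set with the highest mean. Of the 103 called genes given with values, 19 had another tested probe set of the opposite sign. It was called for Eif2s3x, Hbb-y, Igf2r, Tbx3 and Tcf7l1, and did not pass for the other 14: Csf1r, Dbh, Eng, Fkbp4, Id4, Igf1, Isl1, Krt14, Myb, Ncoa2, Nkd2, Rps9, Tnc and Utp14a. Some called genes had another tested probe set of the same sign that did not pass, among them Boc, Col11a1, Mcm2 and Sox9. Gene lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the 27 lists tested of 31 fixed. Camera compares a list with the other genes, whose median difference was -0.12, so its direction can differ from the sign of a list's median. Array measures were compared with an exact permutation test. The design, lists, naming rule and the alternatives other than the last 2 below were fixed before the data were examined. The naming rule took the 10 genes with the largest difference in each direction, up to 4 called members of each list with the largest differences, and a fixed set of genes of the sex chromosomes and tubercle development; lists summarised as a count are not all given examples.

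The method was tested on simulated data over 22519 probe sets with independent normal noise. Of these, 67 were changed by 0.5 on the log2 scale, 67 by 1 and 66 by 2. Recovery was 31.3% of those changed by 0.5, 74.6% of those changed by 1 and 93.9% of those changed by 2. Of 22319 unchanged probe sets 10 were called, 7% of the calls. In the real comparison 40.5% of the probe sets were called, which loosens the adjusted threshold, so these rates do not carry over to it. No pair among the 28 pairs of arrays held identical values. Alternatives were quantile normalization, pseudocounts of 1 and 64, no filter and a filter at the upper quartile, other variance models, array weights, the replicate number as a block, other set tests and leaving out each array, and after seeing the data the 18S control level as a covariate and the comparison without male replicates 1 and 3.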

Results

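The genital tubercle, the embryonic outgrowth that forms the penis or the clitoris, was profiled in male and female mouse embryos of the FVB/N strain at embryonic day 14. RNA of the microdissected tubercle region was amplified and hybridized to Affymetrix MOE430 arrays, with 4 male and 4 female samples and 1 array for each. The table held 45101 probe sets with linear intensities scaled to the same trimmed mean of 1499.6 on every array. The median intensity lay between 184.4 and 206.6 on the female arrays and between 211.7 and 249.4 on the male arrays. The number of arrays limits the precision of each difference, and the p-values measure the spread between these samples, which may be technical in part. Differences are male minus female on the scale of log2(intensity + 16), given with the standard error (SE) of the limma fit, and they understate the change of dim genes. Group levels are mean intensities ± SD with n = 4 per sex.

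Genes of the sex chromosomes were examined first because they check the labels. The Y-linked genes Eif2s3y, which encodes a translation initiation factor subunit, Uty and Kdm5d, which belong to histone demethylase families, were low on the female arrays and higher on every male array. Eif2s3y had an intensity of 48.4 ± 20.1 in females and 5480 ± 950 in males. Its difference was 6.45 ± 0.24 (SE, limma adjusted p = 1.56e-08), that of Uty was 4.99 ± 0.39 and that of Kdm5d was 4.24 ± 0.30. Xist, the noncoding RNA that coats the inactive X chromosome, had 34580 ± 1460 in females and 4307 ± 7820 in males, a difference of -5.15 ± 0.96 (limma adjusted p = 0.00154). The large male SD of Xist came from male replicate 3, which read 16036 on this probe set against 230 to 620 on the other male arrays, while Eif2s3y, Uty and Kdm5d were at the male level on that array.

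**Figure D1:**
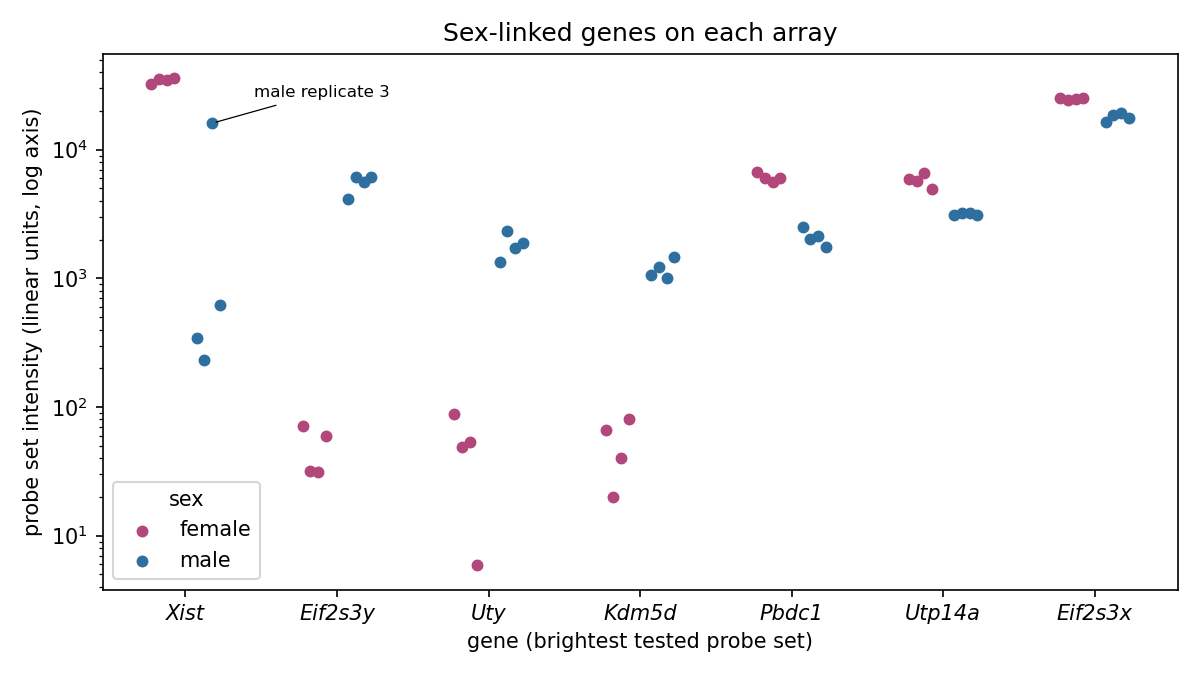
Intensity (log axis) of Xist, of the Y-linked genes Eif2s3y, Uty and Kdm5d and of the X-linked genes Pbdc1, Utp14a and Eif2s3x, with a point for each of the 4 female and 4 male arrays. The Y-linked genes part the sexes on every array, and male replicate 3 holds an Xist intensity of 16036 between the female arrays and the other male arrays.

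X-linked genes that escape inactivation were mostly higher in females where they differed. Of 10 tested members of the list of the X inactivation centre and escape genes, 5 were higher in females, Xist among them, and 0 were higher in males, with 5 adjusted over the list alone. Pbdc1 fell from 6102 ± 477 in females to 2095 ± 307 in males (-1.54 ± 0.12), Utp14a differed by -0.87 ± 0.11, and Eif2s3x, the X-linked partner of Eif2s3y, by -0.47 ± 0.07, with another Eif2s3x probe set called in the opposite direction. Kdm6a, an X-linked histone demethylase, differed by -0.18 ± 0.10 on its brightest probe set and did not pass there (limma adjusted p = 0.152). Another Kdm6a probe set was called higher in males (0.79, limma adjusted p = 0.027). The list as a whole was not called by camera (adjusted p = 0.135; adjusted p = 0.614 with an estimated correlation), nor with the mean of each gene's probe sets (0.594). It was called without male replicate 3, the array with Xist signal (adjusted p = 0.0226), at the upper-quartile filter (0.0419), with the 18S covariate (0.0194) and by fry, which does not compare it with other genes (0.00233). Xist, at -5.15, lowers the mean of the list to -0.81, beside a median of -0.35. Leaving out male replicate 3 makes the Xist difference larger, so that call says little about the escape genes. Over 397 tested X-linked genes without Xist and Tsix the median difference was 0.03, beside -0.12 over 11043 autosomal genes. Camera gave p = 0.00661 for the X-linked genes, and p = 0.177 with an estimated correlation.

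The comparison of male and female tubercles, the question of the series, gave differences across much of the array. Among the genes that rose most in males were Pygo1, a Wnt signalling cofactor, Prox1, a transcription factor of lymphatic endothelium, Aspn and Abi3bp, which encode extracellular matrix proteins, Myom2, a protein of the muscle sarcomere, the X-linked protocadherin gene Pcdh11x and the noncoding host gene Snhg14. Pygo1 rose from 754.7 ± 221 to 4205 ± 1460 (2.43 ± 0.26), Prox1 by 2.32 ± 0.28, Snhg14 by 2.28 ± 0.19, Aspn by 2.20 ± 0.30 and Abi3bp by 2.14 ± 0.42. Pcdh11x (2.56 ± 0.64) and Myom2 (2.24 ± 0.53) also passed, although their male and female ranges overlapped. Among the genes higher in females were Crabp1, a retinoic acid binding protein, Ogfr, a receptor of opioid growth factor, Gcn1, a ribosome-associated regulator of translation, Ppan, a ribosome biogenesis factor, Chtf8, a subunit of a clamp loader of DNA replication, the kinase gene Mapk13, the zinc finger genes Zfp428 and Zfp771, and Ctxn1. Crabp1 fell from 3665 ± 903 in females to 1169 ± 115 in males (-1.61 ± 0.16), Chtf8 differed by -1.83 ± 0.16, Gcn1 by -1.72 ± 0.21, Zfp771 by -1.72 ± 0.19, Ppan by -1.68 ± 0.20, Ogfr by -1.64 ± 0.16, Ctxn1 by -1.63 ± 0.19, Mapk13 by -1.62 ± 0.36 and Zfp428 by -2.05 ± 0.36.

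Of 22519 tested probe sets, 9128 (40.5%) passed at a limma adjusted p under 0.05, 4206 higher in males and 4922 higher in females, and 11190 had an unadjusted p under 0.05. On autosomes, 7742 of 18866 passed. Counted as genes, 4854 of 11489 passed, 1610 higher in males and 3244 higher in females. The balance of directions shifted toward females as brighter probe sets were taken. The share of calls higher in males was 48.9% with no filter, 46.1% in the main test and 42% at the upper-quartile filter. It was 33.2% with the brightest probe set of each gene, adjusted over these alone. The excess among genes thus depends in part on this choice, and its cause was not tested. The ranges of the sexes did not overlap for 37.1% of the tested probe sets, where chance gives 2.9%. The first principal component held 58.8% of the variance and separated the sexes, and correlations between arrays were 0.966 to 0.985 within a sex and 0.904 to 0.952 between the sexes. A technical measure moved with sex as well: the control probe set for 18S ribosomal RNA read 13210 ± 4450 in females and 26740 ± 5680 in males (exact permutation test, two-sided, p = 0.0286, the smallest this design allows, and 0.0715 after adjustment over 5 measures). The median log2 value of the array gave the same 2 p-values, with 7.722 ± 0.066 in females and 7.932 ± 0.119 in males. The scaling to a shared trimmed mean thus left a difference in distribution that followed sex. With the 18S level as a covariate, an alternative chosen after seeing the data, 414 probe sets passed. Of 1512 genes with at least 2 called probe sets, 371 (24.5%) had calls in both directions.

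Steroid hormone signalling genes and their known targets were examined because the tubercle later grows differently under androgens. The estrogen-induced genes that differed were higher in females: 5 of 11 tested members, 0 higher in males, and 5 adjusted over the list alone. Over all tested genes 42.2% passed, 3244 of 4854 higher in females, so the share of members called was near that of all genes. Greb1, an estrogen receptor cofactor, fell from 3528 ± 273 in females to 1628 ± 227 in males (-1.12 ± 0.13), and Myc (-0.58 ± 0.14), Xbp1 (-0.47 ± 0.09) and Myb (-0.42 ± 0.13) were also lower in males. The call of Myb ended without any 1 of 4 arrays (highest limma adjusted p = 0.0805, without female replicate 2). Over all tested genes 1610 of 11489 were called higher in males. Of 11 tested androgen-induced genes, 2 were higher in males, near that share, and 0 higher in females, with 2 adjusted over the list alone. These were Wif1, a secreted Wnt inhibitor (0.50 ± 0.16), and Igf1, a growth factor (0.53 ± 0.17), and neither held without each array. The limma adjusted p rose to 0.0701 for Wif1 without female replicate 2, among 5 arrays that ended its call, and to 0.0689 for Igf1 without male replicate 3. Of 7 tested steroid receptors, steroid enzymes and coregulators, 1 was higher in males and 3 higher in females, 4 in all adjusted over the list alone. The coactivator gene Ncoa2 rose in males (0.58 ± 0.09), and Fkbp4, a chaperone of steroid receptors, was lower (-0.95 ± 0.14), as were Ncoa3 (-0.40 ± 0.11) and Ncoa4 (-0.43 ± 0.11). Esr1, the estrogen receptor alpha gene, differed by 0.31 ± 0.17 and did not pass (limma adjusted p = 0.17). Camera called none of these 3 lists (adjusted p = 0.446, 0.468 and 0.929, in the order given). Fry, which does not compare a list with other genes, called the estrogen-induced list and not the other 2 (adjusted p = 0.00258, 0.693 and 0.0857).

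Hedgehog pathway genes that differed were mostly higher in females. Shh, the ligand made by the urethral epithelium, had 24550 ± 2830 in females and 18740 ± 2620 in males (-0.39 ± 0.11). The receptor component Smo differed by -0.52 ± 0.08, the target and effector Gli1 by -0.88 ± 0.18 and the coreceptor Boc by -0.45 ± 0.15. The call of Boc ended without any 1 of 4 arrays (highest limma adjusted p = 0.0724, without female replicate 3). In the list, 6 of 14 tested members were higher in females and 1 in males, 7 adjusted over the list alone. Most called genes of the whole array were higher in females too, 3244 of 4854. Camera, which compares with the other genes, did not call the list (adjusted p = 0.698), and fry, which does not, called it (adjusted p = 0.00277).

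Other signalling pathways held genes of both directions. In the BMP and TGF-beta list, 7 of 20 tested members were higher in males and 6 in females, 13 adjusted over the list alone. Id4, an inhibitor of basic helix-loop-helix factors, rose in males (1.67 ± 0.13) and Id3 was lower (-1.29 ± 0.15). The receptor gene Bmpr1b rose (1.51 ± 0.22) and the ligand Bmp4 (-0.85 ± 0.18) and the inhibitory Smad6 (-0.97 ± 0.19) were lower. In the Wnt list, 7 of 29 tested members were higher in males and 8 in females, 15 adjusted over the list alone. Among them were Wnt7a at -1.54 ± 0.31, the antagonist Nkd2 falling from 2699 ± 335 in females to 1337 ± 148 in males, Dkk3 at -0.88 ± 0.19 and the transcription factor Tcf7l1 at 1.23 ± 0.27. Another Tcf7l1 probe set was called in the opposite direction. Wnt5a, a ligand of tubercle mesenchyme, differed by -0.07 ± 0.06 on its brightest probe set and did not pass there (limma adjusted p = 0.35). By contrast, 2 other Wnt5a probe sets were called higher in males (0.96 and 0.84, limma adjusted p = 0.0214 and 0.0422). In the FGF list, 3 of 11 were higher in males and 1 in females, 4 adjusted over the list alone. Among them were Fgf7 (0.96 ± 0.25), the feedback inhibitors Spry2 (0.78 ± 0.19) and Spry4 (-0.82 ± 0.23), and the receptor gene Fgfr2 (0.25 ± 0.07), which missed the threshold without female replicate 1 (limma adjusted p = 0.051). Fgf10 differed by 0.37 ± 0.20 and did not pass (limma adjusted p = 0.154). Fgf8 lay below the intensity filter with 6.80 ± 0.81 in females and 7.18 ± 2.46 in males. Camera called none of these lists, with adjusted p = 0.313 for BMP and TGF-beta, 0.953 for Wnt and 0.404 for FGF.

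In the retinoic acid list, 2 of 14 tested members were higher in males and 4 in females, 6 adjusted over the list alone. Besides Crabp1, the binding protein gene Crabp2 was lower in males (-1.06 ± 0.11), and the synthesis enzymes Aldh1a3 (0.82 ± 0.19) and Rdh10 (0.81 ± 0.13) rose. Of 12 tested insulin-like growth factor pathway genes, 2 were higher in males and 5 in females, 8 in all adjusted over the list alone, with Igfbp2 at -0.80 ± 0.14, Irs1 at -0.51 ± 0.11 and Igf2r at -0.65 ± 0.14, where another Igf2r probe set was called in the opposite direction. Of 16 tested Eph receptors and ephrins, 2 were higher in males and 3 in females, 5 adjusted over the list alone. Camera gave these 3 lists an adjusted p of 0.929.

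Several transcription factors that pattern the tubercle were bright in both sexes. Hoxd13, a factor of the distal appendages, had 36380 ± 1960 in females and 29770 ± 1280 in males (-0.29 ± 0.06), and Isl1 had 33690 ± 2710 and 26830 ± 1240 (-0.33 ± 0.07). Pitx1 (-1.03 ± 0.16), Dlx5 (-0.78 ± 0.23) and Tbx2 (-0.76 ± 0.15) were also lower in males, and Tbx3 rose (0.88 ± 0.15), with another of its probe sets called in the opposite direction. Hoxa13 lay below the filter with 200.5 ± 43.5 in females and 161.9 ± 9.41 in males. In this list 3 of 19 tested members were higher in males and 6 in females, 9 adjusted over the list alone, and camera did not call it (adjusted p = 0.929).

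In the skeletal muscle list, 8 of 17 tested genes rose in males, 0 were higher in females and 9 did not pass. The embryonic myosin gene Myh3 rose from 3556 ± 1490 in females to 9134 ± 1880 in males (1.47 ± 0.31), the acetylcholine receptor gene Chrna1 by 1.18 ± 0.17, the actin gene Acta1 by 1.17 ± 0.35 and Ttn, which encodes titin, by 1.13 ± 0.27. The call of Acta1 ended without any 1 of 2 arrays (highest limma adjusted p = 0.0552, without male replicate 2). The count was 9 adjusted over the list alone, and the median difference of the list was 0.69. Camera called the list (adjusted p = 3.64e-05; adjusted p = 0.614 with an estimated correlation), 1 of 4 lists it called. For comparison, 6 of the 35 splits of the arrays into 4 and 4, the real one included, called as many lists; the other 5 put 3 arrays of 1 sex with 1 of the other. In the neuronal list, 5 of 8 tested genes were higher in males, 1 was higher in females and 2 did not pass, 6 adjusted over the list alone, with a median of 0.48 and a camera adjusted p of 0.0268 (adjusted p = 0.614 with an estimated correlation). Stmn2, a microtubule regulator of growing axons, rose by 1.43 ± 0.26, Dbh, an enzyme of noradrenaline synthesis, by 0.61 ± 0.17 and the neurofilament gene Nefm by 0.49 ± 0.12, while Gap43, a growth cone protein, was lower (-0.48 ± 0.17). The call of Gap43 ended without any 1 of 5 arrays (highest limma adjusted p = 0.117, without female replicate 1). The neuronal call missed the threshold without female replicate 3 (adjusted p = 0.0502) and with the mean of each gene's probe sets (adjusted p = 0.128). The 18S control was higher on the male arrays. With it as a covariate camera at the preset correlation of 0.01 still called both lists (adjusted p = 2.69e-12 for skeletal muscle and 0.024 for neurons). Without the covariate, the estimated correlation was 0.487 for skeletal muscle and 0.071 for neurons, above the preset value, so these p-values may be too small. Camera with an estimated correlation was not run with the covariate. Of the muscle and neuronal genes named here, Myh3 (2.62) and Ttn (1.93) kept their own call with the covariate. Chrna1, Acta1, Stmn2, Dbh, Nefm and Gap43 did not.

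In the ribosomal protein list 12 of 16 tested genes were lower in males and 4 did not pass, and in the cell cycle list 11 of 22 were lower and 11 did not pass. Rps9 fell from 20030 ± 3680 in females to 8863 ± 1600 in males (-1.18 ± 0.14) on its brightest probe set, while 2 dimmer Rps9 probe sets lay slightly higher in males and did not pass (0.22 and 0.20, limma adjusted p = 0.399 and 0.414). Rps14 differed by -1.07 ± 0.13, Rpl11 by -0.68 ± 0.20 and Rpl10a by -0.40 ± 0.06. Rpl11 missed the threshold without female replicate 2 (limma adjusted p = 0.0513). None of the 16 ribosomal protein genes was called higher in males, and 12 were called adjusted over the list alone, with a median of -0.28 and a camera adjusted p of 0.00355 (adjusted p = 0.614 with an estimated correlation). Among the cell cycle genes, the cyclin genes Ccne1 (-1.18 ± 0.29) and Ccnb2 (-0.68 ± 0.10), the replication helicase gene Mcm2 (-0.73 ± 0.10) and Birc5 (-0.72 ± 0.20), a mitotic regulator, were lower in males. Of 22 tested members 0 were higher in males, and 11 were called adjusted over the list alone, with a median of -0.27 and a camera adjusted p of 0.0268 (adjusted p = 0.614 with an estimated correlation). The cell cycle call missed the threshold without female replicate 3 (adjusted p = 0.0509) and with the mean of each gene's probe sets (adjusted p = 0.051). The 18S control was lower on the female arrays. With it as a covariate camera at the preset correlation still called the ribosomal protein list (adjusted p = 0.024) and not the cell cycle list (adjusted p = 0.116). The estimated correlation of the ribosomal protein list without the covariate was 0.32, above the preset value, so its p-value may be too small.

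Epithelial, mesenchymal and cartilage genes differed in part. Over all tested genes 42.2% passed, 1610 of 4854 higher in males. The share that passed was lower in the urethral, surface ectoderm and cartilage lists and higher in the mesenchyme and smooth muscle lists. Of 18 tested urethral and simple epithelium genes 4 were higher in females and 0 in males, 4 adjusted over the list alone: the keratin genes Krt8 (-1.15 ± 0.19) and Krt18 (-0.90 ± 0.16), the tight junction gene Cldn6 (-1.07 ± 0.29) and the uroplakin gene Upk1b (-0.66 ± 0.19). Of 16 tested surface ectoderm genes 3 were higher in males and 2 in females, 5 adjusted over the list alone. Krt10, a keratin of differentiating epidermis, rose in males (1.36 ± 0.14), as did the ectodermal transcription factor Trp63 (0.48 ± 0.08), and the basal keratins Krt14 (-0.92 ± 0.17) and Krt5 (-0.75 ± 0.13) were lower. Of 20 tested mesenchyme and matrix genes 5 were higher in males and 6 in females, 12 in all adjusted over the list alone, with Eln at 0.74 ± 0.16, Lum at 0.57 ± 0.14, Pdgfrb at -0.87 ± 0.14 and Tnc at -0.78 ± 0.09. Of 9 tested cartilage and bone genes 3 were higher in males and 0 in females, 3 adjusted over the list alone: Col9a1 (1.69 ± 0.24), the chondrocyte transcription factor Sox9 (1.12 ± 0.16) and Col11a1 (0.83 ± 0.19). Another probe set of Sox9 (0.11) and of Col11a1 (0.09) did not pass (limma adjusted p = 0.717 and 0.705). Camera called none of these lists, with adjusted p = 0.698 for urethral and simple epithelium, 0.446 for surface ectoderm, 0.929 for mesenchyme and 0.0867 for cartilage and bone. The cartilage and bone list was called with no intensity filter (adjusted p = 0.0305), with the 18S covariate (0.024) and by fry (0.00641), but not with the mean of each gene's probe sets (0.405; adjusted p = 0.614 with an estimated correlation). Of 8 tested smooth muscle genes 2 were higher in each sex, 4 adjusted over the list alone (camera adjusted p = 0.313).

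**Figure D2:**
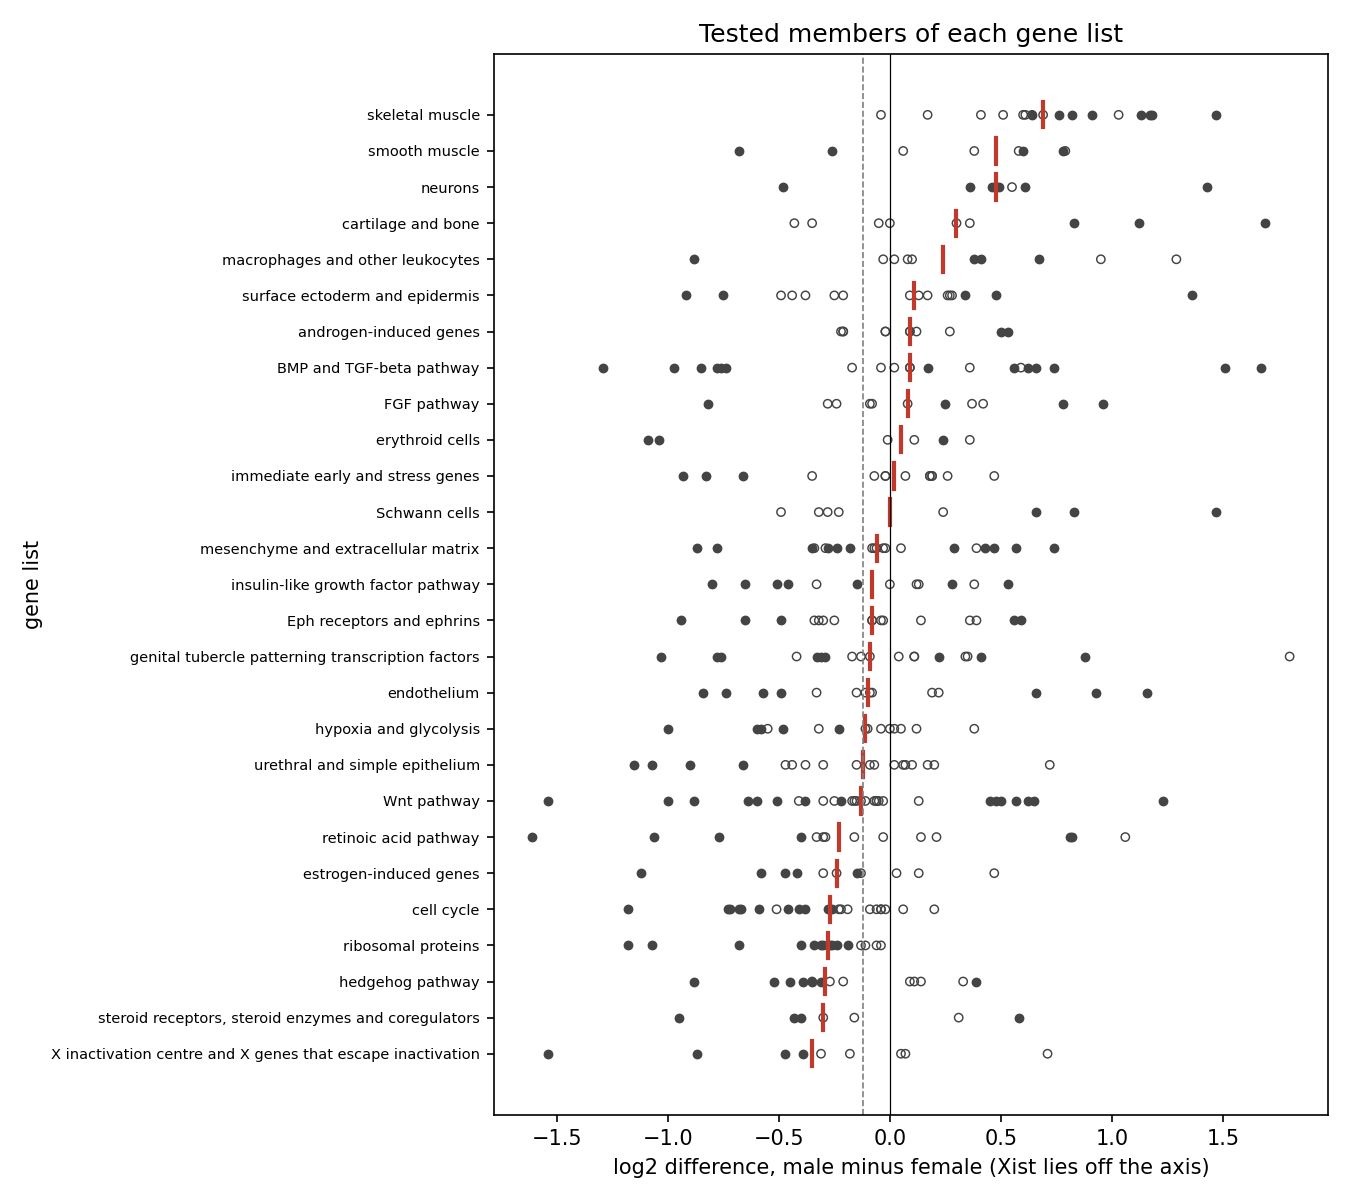
Male minus female log2 difference of each tested gene in the 27 gene lists with at least 5 tested genes, filled where the gene passed the limma test and open where it did not, with the list median as a red bar and the median of all tested genes (-0.12) as a dashed line. Skeletal muscle has the highest median (0.69).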

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

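The tests of integrity, hybridization and amplification and those of the Xist signal, the sorting of the splits by sex and the test of the share of muscle were chosen only after the result was seen; the tests by other splits of the arrays and that of a single array for the muscle genes were set before.

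Among 226 groups of 4 arrays tested, 12 held a value far from the others, about as many as chance gives at 1 in 20. Male replicate 3 read 16036 for Xist (230 to 619.6 on the other male arrays), 862 for Myc (1133 to 1164) and 1287 for Sox9 (1601 to 1665). Male replicate 1 read 685 for Zfp771 (524.4 to 551.3), 579 for Gli1 (399.7 to 420.4), 3506 for Id3 (2500 to 2552), 19721 for Trp63 (23720 to 23890) and 20554 for Rps14 (13600 to 14000). Male replicate 2 read 391 for Chtf8 (313.2 to 324.8) and 1291 for Greb1 (1713 to 1773). Female replicate 4 read 6799 for Wif1 (3903 to 4353), and female replicate 1 read 480 for Dbh (684.8 to 725.9).

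The Xist signal of male replicate 3 appeared on all 3 Xist probe sets, at 63.6%, 45.7% and 19.4% of the gap between the other males and the females. Against a swapped sex label, the lowest ratio of its Y-linked genes Eif2s3y, Uty and Kdm5d to the female mean was 19.5. Against a second X chromosome, its Pbdc1 intensity of 2130 lay below the female mean of 6102, at -8.33 SD of the females. RNA of a female embryo in the sample was neither excluded nor shown: Pbdc1 lay below the level of 2864 that the lowest Xist share needs, at -1.95 SD of the other males, and over 4 escape genes (Kdm5c, Eif2s3x, Utp14a and Pbdc1) the array lay on average 5.1% of the way to the females, below that share but above the bound of 2.8% set for exclusion, with Eif2s3x at 23.7%, Utp14a at 3%, Pbdc1 at 1.2% and Kdm5c at -7.5%. Its mean correlation with the female arrays, 0.923, was the lowest among the males, and no biological explanation from the design was tested.

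Only 1 of the 35 splits of the 8 arrays, the real one, gave as many as 9128 probe sets, and the highest of the others gave 0. For autosomal probe sets the values were 7742 and 0, again 1 of 35. Every other split puts arrays of both sexes into each group, so the difference between the sexes widens the spread within groups. Their 0 calls were thus largely set in advance, and a batch that followed sex would give the same counts. The splits show that the arrays part by sex and not why. Against a uniform shift in hybridization or scanning, the hybridization controls differed on average by 0.05 on the log2 scale, beside a median size of 0.67 among the calls. This mean cannot show a difference that varies from probe set to probe set, so such a difference stays open. Against RNA integrity as the whole cause, 94.6% of the probe sets called in male replicates 1 and 3, which had low beta-actin 3'/5' ratios, against female replicates 1 and 2 kept their sign in the other males against the other females. A difference in amplification between the arrays of the sexes stays open and may account for part of the calls, since 24.5% of genes with at least 2 called probe sets had calls in both directions, and the 18S control level followed sex with r = 0.83 over the 8 arrays. The labels give no amplification batch, and sex itself, the biological difference of the design, also stays open.

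The muscle genes lay above the median tested gene in 17 of 17 cases (100%), which follows from the call of the list and decides nothing about its cause. Against a single array as the cause, the highest adjusted p of the list without each array in turn was 0.00081. A larger share of skeletal muscle in the dissected male tissue and a difference in muscle development between the sexes cannot be told apart here. Both raise these genes and both stay open, as does a difference in amplification that follows sex. Camera with an estimated correlation did not call the list (adjusted p = 0.614).

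Chance was not excluded for the number of gene lists by the count over all splits: 6 of the 35, the real one included, called as many as the real one, which called 4, and the highest of the others called 5. Nor was it excluded for the X-linked genes, where 6 of the 35 splits, the real one included, gave a camera p as small as 0.00661 and the smallest of the others was 3.22e-05. In both cases the other 5 were among the 16 splits that put 3 arrays of 1 sex with 1 of the other and so keep part of the difference between the sexes. Of the 18 splits with 2 arrays of each sex in each group, 0 reached the real value, with at most 3 lists and a smallest camera p of 0.00918. The sexes are balanced in these splits, yet some still called lists or gave a camera p under 0.05 for the X-linked genes. Camera at the preset correlation thus made calls between groups of equal sex makeup, and these splits do not exclude chance either.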

How the results depend on the processing

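The 18S covariate and the comparison without male replicates 1 and 3 were chosen after seeing the data. With the 18S covariate 414 of the 22519 tested probe sets were called, against 9128 without it, 60.6% of them higher in males against 46.1%, and 332 against 7742 on autosomes; 405 of the 9128 calls were kept and 8865 kept their sign. The median size of the calls went from 0.67 to 0.53 and the median SE from 0.15 to 0.27, so the wider error, from the tie of the covariate to sex (r = 0.83), ended most calls along with a smaller difference. Of 103 named called genes, 9 lost the call without some array, Kdm5d and Zfp428 fell below the filter without some array, and 18 passed with the covariate, among them Xist and Myh3. Fewer probe sets were called at the upper-quartile filter (5890), with at least 1.5-fold (5641) and with 1 probe set per gene (4925), which test or admit fewer. Without male replicates 1 and 3, 7963 were called. Leaving out each array gave 7358 to 9468 probe sets and 6237 to 8113 autosomal ones, and every main call that was tested kept its sign. The replicate block gave 8460 probe sets and 7182 autosomal ones. Same-number deviations correlated at -0.126, -0.084, 0.039 and -0.031, so no pairing by number was seen. So few correlations cannot exclude a shared litter or day, which the labels do not give.

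The gene lists called were 4, but 0 with an estimated correlation, 2 with the mean of a gene's probe sets, where neurons and cell cycle lost their call, 3 at the upper-quartile filter (ribosomal proteins, cell cycle and, newly, X inactivation; muscle and neurons untested), 5 with the 18S covariate, 6 with no filter and 13 with fry; without 1 array they were 2 (without female replicate 3) to 5 (without male replicate 3). The X-linked genes, with a median of 0.03, lost their call with an estimated correlation (p = 0.177), which cannot move a median. Their median was 0 with quantile normalization, 0.06 with no filter, 0.1 with the mean of a gene's probe sets, 0.09 with the 18S covariate, 0.06 without male replicates 1 and 3 and 0.01 to 0.05 without 1 array, and camera called them in each; the cause was not tested. Quantile normalization shifted the median difference over tested probe sets from -0.009 to -0.05, away from 0.

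Lists that no camera setting called turned direction as follows, with adjusted p; the cause was not tested except for fry. With the 18S covariate: endothelium 0.672, Eph receptors and ephrins 0.743, patterning transcription factors 0.672 and steroid receptors 0.7. With fry, by construction against 0 and not against other genes: endothelium 0.187, Eph receptors and ephrins 0.00796, erythroid cells 0.187, patterning transcription factors 0.0857, immediate early genes 0.1 and mesenchyme 0.134. With the mean of probe sets: erythroid cells 0.734, patterning transcription factors 0.938 and insulin-like growth factor pathway 0.734. With no filter: endothelium 0.666, Eph receptors 0.748, patterning transcription factors 0.789 and mesenchyme 0.789. Wnt: 0.974 at the upper-quartile filter, 0.917 with pseudocount 1 and 0.957 with quantile normalization, as for insulin-like growth factor (0.957). Without male replicates 1 and 3: endothelium 0.942, patterning transcription factors 0.942 and steroid receptors 0.972. Without 1 array, the direction turned for endothelium without male replicate 1, Eph receptors without female replicate 3, mesenchyme without female replicate 4, patterning transcription factors without male replicate 3, erythroid cells without female replicate 2 or male replicate 1, and Wnt without female replicate 2, 3 or 4 or male replicate 2 or 4. Over all 8 leave-outs adjusted p was 0.773 to 0.991 for endothelium, 0.875 to 0.966 for Eph receptors, 0.833 to 0.993 for mesenchyme, 0.742 to 0.966 for Wnt, 0.875 to 0.989 for erythroid cells and 0.773 to 0.949 for patterning transcription factors.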

Other observations

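The test of gene length was chosen after results had been seen. Blood vessel and blood cell genes went both ways. Of 14 tested endothelial genes 3 were higher in males and 4 in females, 8 in all adjusted over the list alone: the receptor genes Kdr (1.16 ± 0.19) and Tek (0.93 ± 0.16) rose in males, and Erg (-0.74 ± 0.11), an endothelial transcription factor, and Eng (-0.84 ± 0.19) were lower. Of 6 tested erythroid genes 1 was higher in males and 2 in females, 3 adjusted over the list alone: the embryonic globin genes Hba-x (-1.09 ± 0.17) and Hbb-bh1 (-1.04 ± 0.22) were lower in males and Hbb-y was higher (0.24 ± 0.07), with another Hbb-y probe set called in the opposite direction. Of 10 tested macrophage and leukocyte genes 3 were higher in males and 1 in females, 4 adjusted over the list alone, with Mrc1 at 0.67 ± 0.14, Csf1r at 0.38 ± 0.13, whose call ended without any 1 of 4 arrays (highest limma adjusted p = 0.0913, without female replicate 3) and whose 2 other probe sets lay lower in males without passing (limma adjusted p = 0.278 and 0.198), and Cd68 at -0.88 ± 0.26. Camera gave adjusted p = 0.929 for endothelium and erythroid cells and 0.135 for macrophages.

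Among the other lists, Schwann cell genes had 3 of 8 higher in males and 0 in females (3 adjusted over the list alone, camera adjusted p = 0.446), immediate early and stress genes 0 of 14 and 3 (3 adjusted over the list alone, 0.929), and hypoxia and glycolysis genes 0 of 15 and 5 (5 adjusted over the list alone, 0.468). The Y-linked list had 3 tested genes, all higher in males. The remaining lists had too few tested genes for camera: gonad and germ cells 1 of 4 higher in females, kidney and genital ducts 2 of 4 higher in males, and hindgut and intestine 1 of 2 higher in males.

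A hypothesis, prompted by genes that stood out in the data and tested on the same data, was that the difference between the sexes follows gene length. Over 11467 tested genes with a known span, 99.8% of those tested, the male minus female difference and the genomic span had a Spearman rho of 0.18 across genes, which are not independent replicates, between the bounds set for and against such a trend. The median difference was -0.22 in the shortest of 4 equal groups of genes by span (median span 5.55 kb) and 0.00 in the longest (114 kb). Called genes numbered 246 higher in males and 981 higher in females among the shortest, and 565 and 614 among the longest. The test therefore leaves a trend with genomic span open. The span runs from the start to the end of the gene and is not the length of its transcript. Transcript length was not measured, so the test cannot decide whether a step that depends on it contributes.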
